A study of Mus musculus with 8 samples.

How the data were processed

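RNA sequencing measured transcript levels in NMuMG cells, an epithelial line from the mouse mammary gland, in 8 libraries that form 4 groups of 2. The groups cross the RREB1 genotype (WT or KO) with the treatment: 2.5 µM SB505124 for 6 h or 100 pM TGFβ for 1.5 h, after 6 h of serum starvation, per the labels. All KO columns of the deposited table carry the code KO1, which is taken here to mean 1 clone. Per the labels, libraries were made with a TruSeq RNA v2 kit, which does not mark the strand, so reads of genes overlapping on opposite strands are not separated.

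The deposited table holds 1 signal value per gene and library, and the authors' unit is read counts divided by size factors. Per the submitters' processing notes, FastQC 0.11.5, HTSeq 0.6.1p1, DESeq2 3.4 and the mouse build mm10 were used; the aligner is not stated in the sources used here. Each library's values were whole multiples of 1 step (100% within 0.01 reads), so reads and size factors (0.875 to 1.16) were recovered. The size factors differed by at most 0.0054% from median-of-ratios factors computed from those reads. Totals were 25144204 to 32143113 reads. The table has 18102 genes; 26 symbols turned into dates and 4 rows that share a name were kept but not named. Coordinates come from GENCODE M21 on GRCm38, which is mm10, and 94.9% of the symbols were found there (99.5% with RefSeq and older symbols).

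Genes with a mean value of at least 10 were tested (12498 genes). Values were log2 transformed after adding 1, so the log2 fold change of a gene with few reads is understated. A model of the 4 group means was fitted to all 8 libraries with limma 3.58.1 (R 4.3.3) and a variance trend, because 4 residual degrees of freedom are few; the prior added 14.3. The contrasts were TGFβ against SB505124 in each genotype, the difference of these responses (KO minus WT), and KO against WT under each treatment. The TGFβ response averaged over genotypes was also tested, to select genes without using the difference of responses. P-values were adjusted by the Benjamini-Hochberg method over all genes of a contrast, with a threshold of 0.05. Levels are given as mean ± SD of normalised counts with n = 2, and log2 fold changes with the model's SE. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples.

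Gene lists were fixed before the data were examined. The 21 pathway lists were SMAD feedback and co-repressors, EMT transcription factors, fibrogenic ligands and enzymes, extracellular matrix, epithelial junction and identity, mesenchymal markers, ID and BMP targets, cytostatic programme, AP-1 and immediate early, RAS-MAPK output, YAP targets, SRF and actin cytoskeleton, cholesterol synthesis, interferon response, NF-kB and inflammatory, cell cycle, p53 targets, integrated stress and unfolded protein, heat shock, WNT targets and NOTCH targets. The 6 cell type lists held luminal, basal, fibroblast, leukocyte, endothelial and adipocyte markers. Lists with at least 3 tested members were compared with all other genes by camera with a correlation of 0.01, and again with the correlation estimated from the data. The test fry asked whether the members moved one way on balance. The endothelial list had 1 tested member and was not tested, and p-values were adjusted over the 26 other lists. Published work on this pathway shaped the EMT and fibrogenic lists.

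The rule for named genes was also fixed beforehand. Rreb1, Smad7, Skil, Snai1, Has2, Il11 and Cdh1 were named whatever their values. Of these, Snai1, Has2 and Il11 were known from published work on this system. Each comparison added the 10 largest rises and 10 largest falls past the threshold among genes whose groups did not overlap and whose mean reached 50 in the higher group, predicted genes left out. For the difference of responses, the KO response had to lie on the same side of the WT response in all 4 pairings of libraries. Up to 4 members of each list with the smallest p were added. Some genes that this rule names are not reported here. Where a group had no reads of a gene, the fold is a bound computed with 3 reads over the group, and where it had 1 to 3 reads the ratio has an exact 95% counting interval. Intervals are not printed for every ratio. Ratios and bounds come from normalised reads and other folds from the model, so these measures are not comparable with each other. Bounds and intervals cover counting error only. That error is 31.6% for a gene with 10 reads, 10% with 100 and 3.2% with 1000.

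The procedure was tested on simulated data, counts with 200 changed genes at the real means and depths. For the difference of responses limma found 55.2% of genes changed 1.5-fold, 91% of those changed 2-fold and 98.5% of those changed 4-fold, and 2.8% of its calls were unchanged genes. That last share was 3% for TGFβ in WT and 6.3% in KO, and 5.9% and 4.5% for KO against WT under SB505124 and TGFβ. Simulated genes were drawn independently, without shifts between replicates that follow GC content. Each gene's spread was set to the trend of the real data, without a spread of its own. That setting favours a fit with a variance trend, so these shares are not error rates of the real calls. The alternatives fixed beforehand were pseudocounts of 0.5 and 8, no filter or a mean of at least 50, quantile normalisation, rescaling on genes with a mean of at least 100, no variance trend or a robust one, fits to the compared libraries only, the replicate number as a block, a 2-fold minimum, and each library left out. On the recovered reads, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run. A correction of each library for GC content and transcript length (loess, span 0.5, 11922 genes) and a fit without the genes of chromosomes 4 and 14 (11390 genes) were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.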

Results

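Transcript levels were measured by RNA sequencing in NMuMG, a mouse mammary epithelial line in which TGFβ sets off an epithelial-to-mesenchymal transition (EMT). The 8 libraries form 4 groups of 2: WT cells and cells labelled as an RREB1 knockout (KO), each under SB505124, an inhibitor of the TGFβ type I receptor kinase, or under TGFβ. The SB505124 libraries are not untreated, and the treatments lasted 6 h and 1.5 h. WT libraries held 26940914 and 27708227 reads under SB505124 and 26933556 and 25144204 under TGFβ. KO-labelled libraries held 30133445 and 32143113 reads under SB505124 and 30136418 and 27729583 under TGFβ. The first principal component (76.2% of the variance) separated WT from KO-labelled libraries and the second (17.4%) separated the treatments. Ribosomal precursor transcripts (Rn45s) took 1.06% of the reads in WT TGFβ replicate 1 and 0.485% to 0.743% in the other 7 libraries.

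Rreb1, which encodes a zinc finger factor that binds RAS-responsive DNA elements, was read in all 8 libraries. Its normalised count was 1044 ± 15.5 in WT and 1335 ± 11.3 in KO-labelled libraries under SB505124, and 1864 ± 134 and 2361 ± 170 under TGFβ (mean ± SD, n = 2 each). It was higher, not lower, in the libraries labelled KO: by 0.35 ± 0.09 (log2, SE) under SB505124 (limma adjusted p = 0.00153) and by 0.34 ± 0.09 under TGFβ (limma adjusted p = 0.00184). TGFβ raised Rreb1 1.78-fold in WT and 1.77-fold in KO-labelled cells. Counts over the whole gene do not check a small edit that leaves the transcript in place, so the label is used here only as a name.

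**Figure D1:**
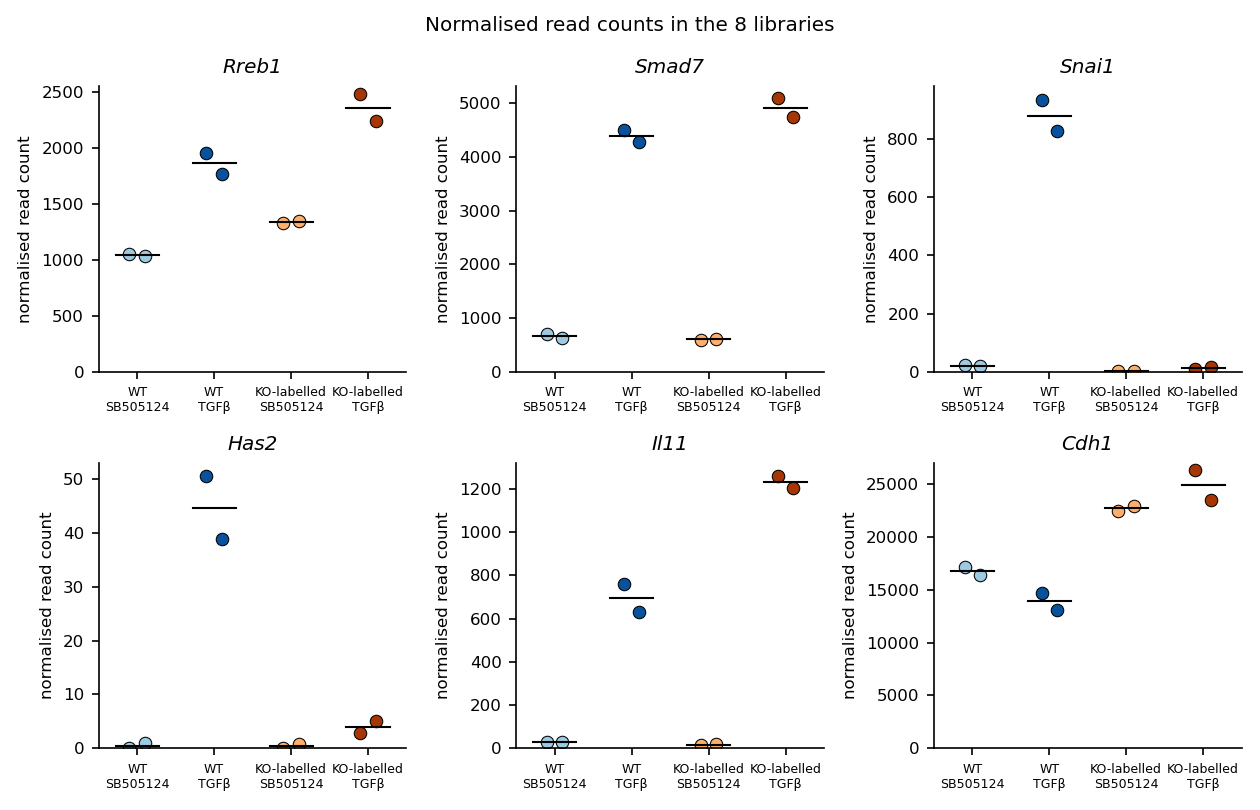
Normalised read counts (y axis) of Rreb1, Smad7, Snai1, Has2, Il11 and Cdh1 in the 4 groups (x axis). Points are single libraries and lines are means of 2 libraries.

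TGFβ in WT cells raised Snai1, which encodes a repressor of E-cadherin, from 21.7 ± 3.75 to 881 ± 77.4, a log2 fold change of 5.29 ± 0.33 (n = 2 against 2, limma adjusted p = 3.2e-10). Il11, a cytokine gene, rose 23.7-fold to 693. The inhibitory SMAD gene Smad7 rose 6.55-fold and the co-repressor gene Skil 6.39-fold. Has2, which encodes a hyaluronan synthase, went from 1 read to a mean of 44.7 (ratio 89.2, interval 15.6 to 3570). Cdh1, which encodes E-cadherin, fell by 0.27 ± 0.09 (16770 to 13900, limma adjusted p = 0.0192). That call was lost in 6 of 22 alternatives, among them each WT SB505124 library left out and the GC and length correction (highest adjusted p 0.138).

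Among the largest rises, the tight junction gene Cldn4 went from 1 read to a mean of 330 (ratio 657, interval 117 to 26000) and Lce1f from 2 reads to 121 (ratio 120, interval 32.7 to 994). Aldh1l1, an enzyme of folate metabolism, rose at least 47.5-fold and the protease gene Prss46 at least 33.7-fold. Fam167a rose 36.1-fold, the immediate early gene Arc 24.4-fold and Arid3a 23.8-fold. Hcar2 (ratio 65.3, interval 17.7 to 545) and the phosphatase gene Dusp2 (ratio 55.5, interval 15 to 464) rose as well. The largest falls in log2 units were those of Arid5b (-3.04), Hs3st1 (-2.81), Cyp1a1 (-2.68), the BMP antagonist gene Grem1 (-2.66), the chemokine genes Cxcl1 (-2.63) and Cxcl5 (-2.48), Pcdh9 (-2.63), Rgs2 (-2.56), Map3k13 (-2.43) and Htr1b (-2.43).

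Of the SMAD feedback genes, 11 of 15 rose and 1 fell (11 and 2 adjusted over the list alone), with Pmepa1 up 9.46-fold and Spsb1 up 9.26-fold. Camera placed them above other genes (adjusted p = 1.4e-07, and adjusted p = 0.298 with an estimated correlation). Of the fibrogenic genes, 12 of 16 rose and 1 fell (12 and 1 adjusted over the list alone), among them Ctgf (4.46-fold) and Pdgfa (4.41-fold; adjusted p = 1.3e-07, and adjusted p = 0.499 with an estimated correlation). Of the EMT factors, 7 of 13 rose and 1 fell (7 and 1 adjusted over the list alone), with Sox9 up 4.84-fold and Foxq1 up 4.37-fold (adjusted p = 0.024, and adjusted p = 0.484 with an estimated correlation). Published work on this pathway shaped the EMT and fibrogenic lists, so their direction is not independent evidence. RAS-MAPK output went down, with 11 of 15 members falling and 2 rising (11 and 2 adjusted over the list alone), among them Spry1 (-2.02), Epha4 (-1.01) and Dusp6 (-0.96). Its camera adjusted p was 0.0082 (adjusted p = 0.499 with an estimated correlation) and the call was lost without the genes of chromosomes 4 and 14 (0.0546).

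The other 22 lists were not called in WT. Members that rose and fell numbered 9 and 6 of 20 AP-1 and immediate early genes (Junb 2.48, Fosl1 -1.08), 5 and 7 of 14 YAP targets (F3 2.33, Ankrd1 -0.87) and 5 and 5 of 14 epithelial genes (Elf3 2.31, Ocln -0.58). They numbered 3 and 2 of 12 extracellular matrix genes (Col1a1 3.53, Col4a1 -0.39), whose median of -0.11 and mean of 0.26 differ in sign, and the YAP targets also had a median of -0.20 against a mean of 0.17. Of the mesenchymal markers 2 rose and 1 fell of 8 (Itga5 1.34, Cdh2 -0.79), and of the ID and BMP targets 2 and 4 of 9 (Id2 -1.86, Atoh8 -2.39). Of the cytostatic genes 5 rose and 3 fell of 11 (Cdkn1a 0.94). Of the NF-kB genes 3 rose and 5 fell of 14 (Csf2 2.42, Ccl20 -2.31), of the cholesterol genes 1 and 8 of 18 (Idi1 -0.97), and of the stress genes 3 and 10 of 15 (Ddit3 -1.06). Further counts were 6 and 1 of 13 SRF and actin genes, 2 and 4 of 18 interferon genes, and 2 and 5 of 20 cell cycle genes. The p53 targets had 5 and 6 of 14, and there were 4 and 5 of 10 heat shock genes, 3 and 1 of 8 WNT targets (Wnt9a 2.67) and 3 and 2 of 8 NOTCH targets (Dll1 2.39, Jag1 1.97). Of the cell type markers, 2 and 1 of 6 luminal, 3 and 1 of 4 basal, 2 and 0 of 3 fibroblast, 0 and 1 of 6 leukocyte and 1 and 0 of 3 adipocyte genes rose and fell. In all, limma called 5416 of 12498 genes in WT, 2520 higher and 2896 lower under TGFβ. At least 2-fold, 455 were higher and 295 lower.

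TGFβ in KO-labelled cells raised Snai1 only from 2.66 ± 1.13 to 13.1 ± 6.2, a log2 fold change of 1.90 ± 0.33 (n = 2 against 2, limma adjusted p = 1.9e-04), on 6 reads under SB505124 and 26 under TGFβ. Il11 rose 68.6-fold, from 17 ± 1.64 to 1231 ± 40.1. Smad7 rose 8.13-fold and Skil 7.63-fold. Has2 went from 1 read to a mean of 4.01 (ratio 8.87, interval 1.19 to 393, limma adjusted p = 0.0492), a call lost in 10 of 21 alternatives. Cdh1 did not pass (22690 ± 353 and 24900 ± 2065, limma adjusted p = 0.286).

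Cldn4 rose from 2 reads to a mean of 489 (ratio 544, interval 150 to 4500), Lce1f 57.5-fold, Fam167a 43.8-fold, Arid5a 33.3-fold and the fructose transporter gene Slc2a5 31-fold. The receptor gene Hcar2 (ratio 72, interval 19.5 to 601), G0s2 (23.6-fold), Arid3a (22.3-fold) and the receptor kinase gene Mst1r (22.1-fold) also rose. The largest falls in log2 units were those of Trim71 (-3.44), Cxcl1 (-3.10), Hs3st1 (-3.04), Cxcl5 (-2.96), Clec2d (-2.84), Angptl4 (-2.68), Exph5 (-2.65), Otud1 (-2.61), the insulin receptor substrate gene Irs1 (-2.47) and Usp17la (-2.34).

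Camera called 11 lists in KO-labelled cells, all upward. Of the SMAD feedback genes 12 of 15 rose and 1 fell (12 and 2 adjusted over the list alone), with Spsb1 up 19.4-fold (adjusted p = 3.7e-11, and adjusted p = 0.117 with an estimated correlation). Of the fibrogenic genes 12 of 16 rose and 1 fell (12 and 1 adjusted over the list alone), with Pdgfb up 3.71-fold (adjusted p = 3.2e-10, and adjusted p = 0.258 with an estimated correlation). Of the AP-1 and immediate early genes 13 of 20 rose and 2 fell (14 and 3 adjusted over the list alone), with Junb up 9.02-fold, Fos 3.38-fold and Jun 2.42-fold (adjusted p = 2.9e-05, and adjusted p = 0.196 with an estimated correlation). Of the EMT factors 8 of 13 rose and none fell (10 and 0 adjusted over the list alone), with Sox9 up 7.43-fold (adjusted p = 4.9e-05, and adjusted p = 0.117 with an estimated correlation). WNT targets had 5 up and 1 down of 8 (the same adjusted over the list alone), with Wnt9a up 7.52-fold (adjusted p = 0.00168, and adjusted p = 0.317 with an estimated correlation). Epithelial genes had 7 up and 2 down of 14 (8 and 2 adjusted over the list alone), with Elf3 up 3.02-fold (adjusted p = 0.0022, and adjusted p = 0.258 with an estimated correlation).

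Extracellular matrix genes had 4 up and 0 down of 12 (the same adjusted over the list alone), with Col1a1 up 16.7-fold and Col5a1 up 3-fold (adjusted p = 0.00774, and adjusted p = 0.456 with an estimated correlation). SRF and actin genes had 6 up of 13, with Zyx up 2.14-fold, and fibroblast markers 2 up of 3, with Pdgfra up 3.45-fold, with the same counts adjusted over the list alone (adjusted p = 0.0187 each, and adjusted p = 0.317 with an estimated correlation). Mesenchymal markers had 4 up and 1 down of 8 (5 and 1 adjusted over the list alone), with Itga5 up 4.72-fold (adjusted p = 0.02, and adjusted p = 0.317 with an estimated correlation). Cytostatic genes had 7 up and 1 down of 11 (7 and 2 adjusted over the list alone), with Klf10 up 3.12-fold (adjusted p = 0.0295, and adjusted p = 0.258 with an estimated correlation). The mesenchymal and cytostatic calls were lost without the genes of chromosomes 4 and 14 (adjusted p = 0.0616 each), the mesenchymal one also without KO TGFβ replicate 1 (0.0614), and the SRF call without KO SB505124 replicate 1 (0.0513) or after the GC and length correction (0.0682).

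The other 15 lists were not called. Members that rose and fell numbered 4 and 7 of 15 RAS-MAPK genes (Dusp5 1.22, Spry1 -2.11), 5 and 4 of 14 YAP targets (F3 2.50), 4 and 4 of 9 ID and BMP targets (Id2 -0.95), 1 and 7 of 18 cholesterol genes (Insig1 0.73, Hmgcs1 -0.66) and 4 and 5 of 15 stress genes (Trib3 1.99, Dnajb9 -0.85). They numbered 2 and 3 of 18 interferon genes, 4 and 5 of 14 NF-kB genes (Csf2 3.02), 0 and 1 of 20 cell cycle genes (Bub1 -0.38), 4 and 4 of 14 p53 targets, 2 and 3 of 10 heat shock genes and 3 and 3 of 8 NOTCH targets (Dll1 3.95, Notch1 -0.99). Of the cell type markers, 2 and 2 of 6 luminal, 1 and 0 of 4 basal, 0 and 1 of 6 leukocyte and 0 and 1 of 3 adipocyte genes rose and fell. In all, limma called 3864 genes in KO-labelled cells, 1888 higher and 1976 lower. At least 2-fold, 537 were higher and 175 lower. The count was 2320 without KO TGFβ replicate 2 (1293 higher, 1027 lower) and 2332 without KO SB505124 replicate 1 (1315 higher, 1017 lower).

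**Figure D2:**
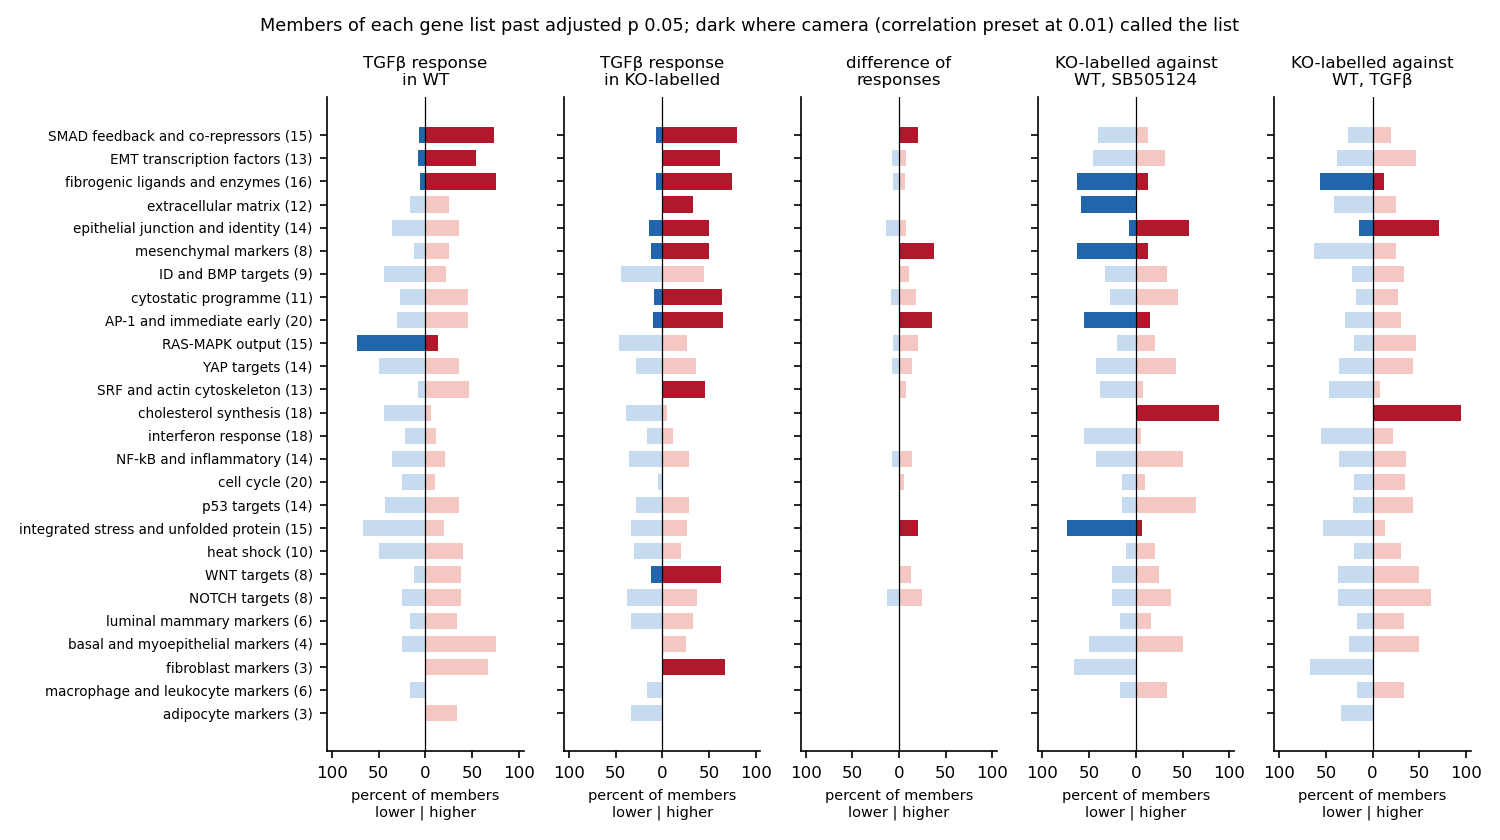
Percent of list members that were higher (right) or lower (left) in each comparison (x axis) for each gene list (y axis). Bars are lists, dark where camera called the list.

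Of the genes called in WT, 54.4% of the rises and 54.1% of the falls were also called in KO-labelled cells. Of those called in KO-labelled cells, 72.6% of the rises and 79.3% of the falls were also called in WT. Both genotypes raised 1371 genes (380.7 if calls were independent) and lowered 1566 (457.9 if independent), 24 genes were called in opposite directions, and the responses correlated with a Pearson r of 0.80 across genes. Of the 3063 genes that rose in the averaged response, 54.4% rose less in KO-labelled cells (median difference -0.03). Of the 508 that rose at least 2-fold, 34.6% rose less. Of the 3414 that fell, 68.2% fell less in KO-labelled cells (median difference 0.09), and of the 207 that fell at least 2-fold, 56.5% did. By fry neither set moved one way past the threshold of 0.05. Simulated responses equal in both genotypes, with fewer genes called (1025 rises and 990 falls), gave 49.8% and 50.3%. Independently drawn genes with equal responses must give nearly even shares. The simulation held no shifts between replicates, so it does not show how far the real shares could stray without a difference.

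Among the genes named in advance, Snai1, Has2 and Il11 were known from published work on this system, so their results are not blind. The response of Snai1 was lower by a log2 difference of -3.39 ± 0.47 in KO-labelled cells (n = 2 per group, limma adjusted p = 3.1e-04). Without a variance trend the adjusted p was 0.0612. Il11 responded more strongly, by 1.54 ± 0.22 (limma adjusted p = 3.8e-04). The differences for Has2 (-3.16, adjusted p = 0.0903), Cdh1 (0.40, adjusted p = 0.0961), Smad7 (0.31, adjusted p = 0.182), Skil (0.26, adjusted p = 0.284) and Rreb1 (-0.01, adjusted p = 0.976) did not pass.

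The largest differences toward KO were those of Gde1 (2.80), Paqr9 (2.59), the cadherin-family gene Fat2 (2.49), the BMP ligand gene Bmp8a (2.24), the transcription factor genes Onecut3 (2.20) and Dlx3 (1.90), Card14 (1.90), the channel gene Trpm1 (1.90), Fam65c (1.74) and Mst1r (1.72). Gde1 had no reads in KO-labelled cells under SB505124 and a mean of 9.49 under TGFβ, against 825 and 1229 in WT. Toward WT were Aldh1l1 (-3.78), the adhesion scaffold gene Nedd9 (-2.11), Ppfibp2 (-1.98), Cpn1 (-1.88), Angptl4 (-1.76), Clec2d (-1.62), the adhesion receptor gene Gpr56 (-1.46), and the cytokine genes Il15 (-1.30) and Csf3 (-1.16). Nedd9 rose from 241 to 1044 in WT and stood at 662 and 661 in KO-labelled cells. The calls of Fam65c (10 of 19), Il15 and Csf3 (9 of 21 each), Paqr9 (6 of 20), Dlx3 (6 of 21), Cpn1 (5 of 21), Onecut3 (3 of 20) and Trpm1 (2 of 20) were lost in some alternatives. Those of Gde1 and Mst1r were lost in 1 of 21. Groups without reads leave the size of a difference open: Gde1 ranged from 0.55 with a pseudocount of 8 (adjusted p = 0.194) to 5.67 in edgeR, and Aldh1l1 from -6.59 to -1.80.

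Of the AP-1 and immediate early genes, 7 of 20 had a higher response in KO-labelled cells and none a lower one (10 and 2 adjusted over the list alone), among them Fos (1.53), Klf4 (1.10), Rhob (0.74) and Fosl2 (0.72; camera adjusted p = 1.0e-05, and adjusted p = 0.37 with an estimated correlation). SMAD feedback genes had 3 higher and 0 lower of 15 (4 and 0 adjusted over the list alone), namely Spsb1 (1.07), Tgfbr1 (0.72) and Smurf1 (0.50; adjusted p = 2.5e-04, and adjusted p = 0.37 with an estimated correlation). Stress genes had 3 higher of 15 (6 and 0 adjusted over the list alone), namely Trib3 (1.28), Chac1 (1.16) and Vldlr (0.95; adjusted p = 0.00122, and adjusted p = 0.37 with an estimated correlation). Mesenchymal markers had 3 higher of 8 (3 and 1 adjusted over the list alone), namely Itga5 (0.90), Mmp14 (0.55) and Cdh2 (0.49; adjusted p = 0.00566, and adjusted p = 0.37 with an estimated correlation). No extracellular matrix gene passed of 12 (6 and 1 adjusted over the list alone), although camera called the list (adjusted p = 0.00566, and adjusted p = 0.695 with an estimated correlation). By fry the last 2 lists were not called (adjusted p = 0.0636 and 0.231), and the matrix list was also lost without WT TGFβ replicate 2. The cytostatic list was called by fry (adjusted p = 0.0209) but not by camera (adjusted p = 0.469). Under SB505124 camera called the AP-1, stress, mesenchymal and matrix lists lower in KO-labelled libraries (medians -0.5, -0.48, -0.66 and -0.31). Under TGFβ their medians were -0.08, -0.26, -0.6 and -0.32, and camera called none of them. Whether the lower start accounts for their larger response was not tested.

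The other 21 lists were not called by camera. Single members differed in the EMT list (Hmga2 0.72 higher, Snai1 lower), the fibrogenic list (Il11 higher, Ctgf -1.04), the epithelial list (Esrp2 0.45, Ehf -0.74, Elf3 -0.71), the RAS-MAPK list (Dusp5 1.13, Spred2 0.83, Dusp4 0.65, Dusp6 -0.50) and the NOTCH list (Dll1 1.56, Jag1 0.60, Hes1 -0.64). The same held for the cytostatic list (Klf10 0.69, Gadd45b 0.58, Foxo1 -0.46), the YAP list (Nt5e 0.53, Crim1 0.55, Ctgf), the NF-kB list (Ccl20 0.63, Csf1 0.57, Cxcl5 -0.49), and for Id2 (0.91), Actn1 (0.52), Plk1 (0.47) and Wnt7a (0.68), each alone in the ID and BMP, SRF, cell cycle and WNT lists. No member passed in the cholesterol, interferon, p53, heat shock, luminal, basal, fibroblast, leukocyte or adipocyte lists. The EMT list had a median of 0.31 and a mean of -0.02. In all, limma called 352 genes, 281 higher and 71 lower in KO-labelled cells. Of these, 117 were called in both genotypes with a larger response in KO and 70 with a larger one in WT. Further, 48 and 29 rose in KO only and in WT only, 4 and 60 fell in KO only and in WT only, and 24 moved in opposite directions. The count was 47 without a variance trend, 134 without a filter and 666 after the GC and length correction, and it ranged from 141 to 1027 with single libraries left out.

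**Figure D3:**
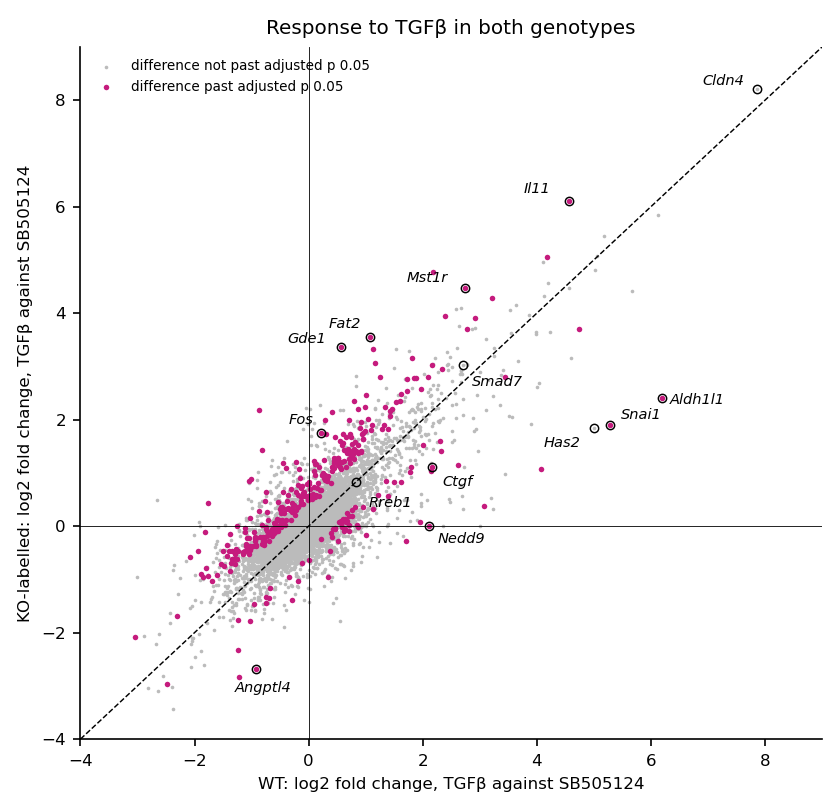
Log2 response to TGFβ in WT (x axis) and in KO-labelled cells (y axis). Points are genes, coloured where the difference of responses had an adjusted p below 0.05, and the dashed line marks equal responses.

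KO-labelled against WT libraries under SB505124 showed lower Snai1 (2.66 ± 1.13 against 21.7 ± 3.75, log2 -2.66 ± 0.33, n = 2 against 2, limma adjusted p = 1.4e-06). Il11 was lower (-0.70), while Skil was higher by 0.47 and Cdh1 by 0.44 (22690 ± 353 against 16770 ± 520). Smad7 (-0.15, adjusted p = 0.141) and Has2 (1 read in each genotype) did not pass.

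Many genes had few or no reads in one genotype. The kinase gene Ttbk1 went from 2 reads in WT to a mean of 1198 (ratio 1190, interval 330 to 9850), and the carboxylesterase gene Ces1d was at least 190-fold higher, Iyd at least 132-fold, Gsdma at least 100-fold and the calcium channel gene Cacng7 at least 98.7-fold. Jakmip2 (ratio 482), the catenin gene Ctnna2 (ratio 493), Dach2 (ratio 321), Ces1g (ratio 293) and the chromatin organiser gene Satb1 (69.8-fold) were also higher. The amino acid transporter gene Slc38a1 went from 3631 to 1 read (ratio 8100, interval 1450 to 320000), and Mal2 was at least 737-fold lower, Gde1 at least 614-fold and Slc35f2 at least 488-fold. Adcy1 (ratio 1080), the keratin gene Krt7 (log2 -8.71), Micu2 (1070 to 2.23), Atp9a (3357 to 9.34) and Trim47 (601 to 1.86) were lower as well.

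Genes of chromosomes 4 and 14 were lower as a body. The median log2 difference was -0.69 over 716 genes of chromosome 4 (90.5% lower) and -0.62 over 392 genes of chromosome 14 (86.2% lower), against 0.25 on chromosome 18 and -0.07 to 0.15 on the others in both treatments. Under TGFβ the medians were -0.68 and -0.58. Micu2, Plau, Jun, Klf4 and Tnc lie on these 2 chromosomes.

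**Figure D4:**
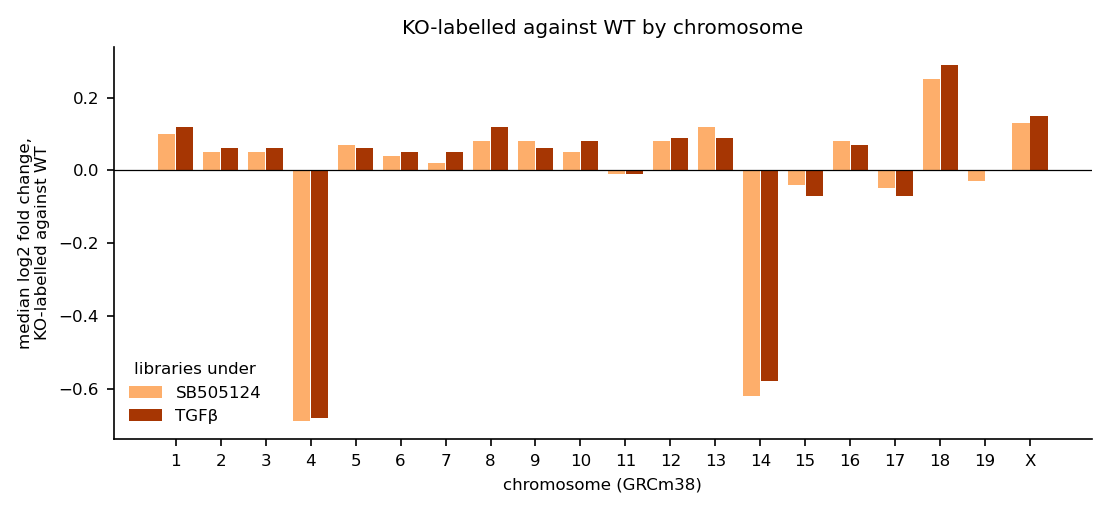
Median log2 difference between KO-labelled and WT libraries (y axis) per chromosome (x axis), under SB505124 and under TGFβ. Bars are medians over the tested genes of a chromosome.

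Cholesterol synthesis genes were higher, 16 of 18 with none lower (the same adjusted over the list alone), among them Stard4 (2.78-fold), Hmgcs1 (2.38-fold), Cyp51 (1.89-fold) and Nsdhl (1.82-fold; camera adjusted p = 1.8e-05, and adjusted p = 0.268 with an estimated correlation). Epithelial genes were higher, 8 of 14 with 1 lower (the same adjusted over the list alone), with Ehf up 32.4-fold, Ocln 3.06-fold and Dsp 1.94-fold (adjusted p = 0.0316, and adjusted p = 0.512 with an estimated correlation). Stress genes were lower, 11 of 15 with 1 higher (the same adjusted over the list alone), with Trib3 at -2.41 and Chac1 at -2.18 (adjusted p = 0.00468, and adjusted p = 0.512 with an estimated correlation). Fibrogenic genes were lower, 10 of 16 with 2 higher (the same adjusted over the list alone), with Plau at -3.45 and Tgfb1 at -2.18 but Wisp1 at 1.48 (adjusted p = 0.00772, and adjusted p = 0.624 with an estimated correlation). Extracellular matrix genes were lower, 7 of 12 with 0 higher (the same adjusted over the list alone), with Col6a1 at -4.77, Tnc at -4.61 and Col5a1 at -3.92 (adjusted p = 0.011, and adjusted p = 0.586 with an estimated correlation).

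AP-1 and immediate early genes were lower, 11 of 20 with 3 higher (11 and 4 adjusted over the list alone), with Klf4 at -1.96 and Jun at -1.71 (adjusted p = 0.0314, and adjusted p = 0.512 with an estimated correlation). Mesenchymal markers were lower, 5 of 8 with 1 higher (the same adjusted over the list alone), with Itga5 at -2.50 and Vim at -1.27 (adjusted p = 0.0316, and adjusted p = 0.512 with an estimated correlation). The epithelial call was lost without KO SB505124 replicate 2 (0.0708) and without the genes of chromosomes 4 and 14 (0.0587), and the AP-1 call after the GC and length correction (0.0731).

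The other 19 lists were not called under SB505124. Members higher and lower numbered 2 and 6 of 15 SMAD feedback genes (Ldlrad4 -4.79), 4 and 6 of 13 EMT factors (Snai3 1.78, Hmga2 -1.14), 3 and 3 of 9 ID and BMP targets, and 5 and 3 of 11 cytostatic genes (Klf10 -1.77). There were 3 and 3 of 15 RAS-MAPK genes (Epha2 -1.55), 6 and 6 of 14 YAP targets and 1 and 5 of 13 SRF and actin genes (Vcl -1.04). They numbered 1 and 10 of 18 interferon genes (Ifit2 0.86, Irf9 -1.28), 7 and 6 of 14 NF-kB genes (Ccl20 1.40), and 2 and 3 of 20 cell cycle genes. There were 9 and 2 of 14 p53 targets (Trp53inp1 1.22), 2 and 1 of 10 heat shock genes, 2 and 2 of 8 WNT targets (Wnt7a -2.92) and 3 and 2 of 8 NOTCH targets (Notch1 2.02). Of the cell type markers, 1 and 1 of 6 luminal (Foxa1 -4.11), 2 and 2 of 4 basal (Mylk 1.52), 0 and 2 of 3 fibroblast, 2 and 1 of 6 leukocyte (Cd14 1.50) and 0 and 0 of 3 adipocyte genes were higher and lower. In all, limma called 7117 genes, 3655 higher and 3462 lower in KO-labelled libraries. At least 2-fold, 839 were higher and 1041 lower.

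KO-labelled against WT libraries under TGFβ showed Snai1 at 13.1 ± 6.2 against 881 ± 77.4 (log2 -6.04 ± 0.33, n = 2 against 2, limma adjusted p = 1.6e-11) and Has2 at 4.01 ± 1.58 against 44.7 ± 8.25 (log2 -3.21, limma adjusted p = 4.9e-04). Il11 was 1.78-fold higher, Cdh1 1.79-fold (24900 ± 2065 against 13900 ± 1104) and Skil 1.65-fold. Smad7 (0.16, adjusted p = 0.0973) did not pass.

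Ces1d was at least 139-fold higher, Ctnna2 at least 137-fold, Dach2 at least 90-fold and Cacng7 at least 85.2-fold, and Ttbk1 was 218-fold higher, Jakmip2 189-fold and Cyp2c70 93.3-fold. Gsdma (ratio 401), Iyd (ratio 195) and Satb1 (ratio 169) were higher too. A ratio under 1 treatment is not comparable with a model fold under the other. The model's log2 fold changes under SB505124 and TGFβ were 9.433 and 7.765 for Ttbk1, and 6.125 and 6.747 for Satb1. Slc35f2 was at least 396-fold lower and Lmo1, a LIM-domain gene, at least 209-fold, with Slc38a1 (ratio 3100), Adcy1 (ratio 1720), the G protein gene Gnb4 (ratio 1270), Mal2 (ratio 838), the B cell linker gene Blnk (ratio 631), Atp9a (3426 to 5.48), Krt7 (11790 to 24.9) and Micu2 (1247 to 2.5).

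Cholesterol synthesis genes were again higher, 17 of 18 with none lower (the same adjusted over the list alone), with Idi1 up 3.07-fold and Insig1 1.9-fold (camera adjusted p = 9.9e-06, and adjusted p = 0.248 with an estimated correlation). Epithelial genes were higher, 10 of 14 with 2 lower (the same adjusted over the list alone), with Ehf up 19.4-fold and Ocln 3.67-fold but Pkp3 at -2.56 (adjusted p = 0.0402, and adjusted p = 0.953 with an estimated correlation). Fibrogenic genes were lower, 9 of 16 with 2 higher (10 and 2 adjusted over the list alone), with Plau at -3.30 and Timp1 at -1.16 (adjusted p = 0.0402, and adjusted p = 0.953 with an estimated correlation). The epithelial and fibrogenic calls were lost without the genes of chromosomes 4 and 14 (0.0736 each), and the fibrogenic one also after quantile normalisation (0.0511) and without WT TGFβ replicate 1 (0.117) or KO TGFβ replicate 2 (0.0844).

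The other 23 lists were not called under TGFβ. Members higher and lower numbered 3 and 4 of 15 SMAD feedback genes, 6 and 5 of 13 EMT factors (Sox4 1.48), 3 and 5 of 12 matrix genes, 2 and 5 of 8 mesenchymal markers (Cdh2 1.19, Vim -1.09), 3 and 2 of 9 ID and BMP targets (Id2 1.68), 3 and 2 of 11 cytostatic genes and 6 and 6 of 20 AP-1 genes (Jund 1.78). They numbered 7 and 3 of 15 RAS-MAPK genes, 6 and 5 of 14 YAP targets (Ctgf -0.82), 1 and 6 of 13 SRF and actin genes, 4 and 10 of 18 interferon genes, and 5 and 5 of 14 NF-kB genes (Ccl20 2.03). There were 7 and 4 of 20 cell cycle genes, 6 and 3 of 14 p53 targets and 2 and 8 of 15 stress genes (Atf4 -0.81). They numbered 3 and 2 of 10 heat shock genes, 4 and 3 of 8 WNT targets and 5 and 3 of 8 NOTCH targets (Notch1 2.33), and 2 and 1 of 6 luminal, 2 and 1 of 4 basal, 0 and 2 of 3 fibroblast, 2 and 1 of 6 leukocyte and 0 and 1 of 3 adipocyte markers. In all, limma called 7865 genes, 4087 higher and 3778 lower in KO-labelled libraries. At least 2-fold, 1009 were higher and 1047 lower. Both treatments shared 3154 genes called higher (1195.2 if independent) and 2900 called lower (1046.5 if independent), with 28 in opposite directions and a Pearson r of 0.95 across genes.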

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

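The tests of copy number and of the loss of RREB1 as sources of the chromosome pattern, and all 3 tests on Snai1 and both tests on the AP-1 list were chosen only after these results were seen. Genes of chromosomes 4 and 14 were lower in the KO-labelled libraries in both treatments. GC content or transcript length could shift groups of genes, but after the correction the highest of the 4 medians was still -0.64. A lower copy number of both chromosomes in the KO-labelled line would lower each part of them, and the highest median of their blocks was -0.45. With 90.5% and 86.2% of their genes lower under SB505124, that value largely restates the pattern, so it leaves copy number open. Whether the loss of RREB1 itself may be the source cannot be told apart from a trait of the clone. All KO-labelled libraries carry the code KO1, taken here to mean 1 clone, so no second clone is known to compare.

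Snai1 rose less in the KO-labelled libraries (difference of the log2 responses -3.39). A weaker TGFβ response as a whole could lower it, but the SMAD feedback genes that rose in WT had a median difference of 0.31, and of 11 such genes 1 rose less. Low read counts could understate the ratio, but its upper counting bound in KO-labelled libraries was 14.3, below the lower bound of 30.1 in WT. These bounds pool the reads of both replicates and cover counting error only, not the spread between replicates. A lost segment of DNA could remove it: the 20 nearest tested genes had a median of -0.10, which speaks only against a loss of that whole stretch, and 1 of them, Atp9a, chosen here after its values were seen, was nearly absent. A smaller lost segment, a loss of RREB1 function and another trait of the clone remain possible sources.

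The AP-1 and immediate early list responded more in the KO-labelled libraries (camera adjusted p = 1e-05, and adjusted p = 0.37 with an estimated correlation). A bias of GC content or transcript length could produce this, but after the correction the camera adjusted p was 4.16e-05. The correction lowered the median difference of the list from 0.63 to 0.47, so this bias may contribute to the larger response. A single library could produce it, but with each left out in turn the highest adjusted p was 5.03e-05. The list also started lower in KO-labelled libraries under SB505124 (median -0.50) and stood at -0.08 under TGFβ, so a lower start may contribute to the larger response.

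The difference of responses itself was tested for the following genes and lists, given as KO minus WT in log2 units. Toward KO were Gde1 (2.80), Paqr9 (2.59), Fat2 (2.49), Bmp8a (2.24), Onecut3 (2.20), Dlx3 (1.90), Card14 (1.90), Trpm1 (1.90), Fam65c (1.74), Mst1r (1.72), Il11 (1.54), Arid5b (0.96) and Arid5a (0.87). Toward WT were Cxcl5 (-0.49), Csf3 (-1.16), Il15 (-1.30), Gpr56 (-1.46), Clec2d (-1.62), Angptl4 (-1.76), Cpn1 (-1.88), Ppfibp2 (-1.98), Nedd9 (-2.11) and Aldh1l1 (-3.78). Of these, Fam65c lost its call in 10 of 19 alternatives, Il15 and Csf3 in 9 of 21, Paqr9 in 6 of 20, Dlx3 in 6 of 21 and Cpn1 in 5 of 21. Camera adjusted p-values of the other lists were 0.00025 for SMAD feedback, 0.0012 for integrated stress, and 0.0057 each for extracellular matrix and mesenchymal markers (adjusted p = 0.37, 0.37, 0.695 and 0.37 with an estimated correlation). Of these, the stress, matrix and mesenchymal lists were also called lower in KO-labelled libraries under SB505124 and were not called under TGFβ. Of the 35 splits of the 8 libraries into 4 and 4, with genotype added to the model, 1 called as many genes as the treatment did (5868), namely the treatment itself, and 1 was not estimable. The highest of the other splits called 0, but each of them leaves the treatment effect in its residual spread, so few calls were to be anticipated from them whatever the cause. Without a genotype term the treatment called 1057 genes and the split by genotype 5917, so genotype is the larger structure of the samples. The averaged response called 6477 genes in the model of 4 group means, which also fits the difference of responses.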

How the results depend on the processing

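The GC and length correction and the fit without chromosomes 4 and 14 were chosen only after the data were seen. No called list, and no called gene among those picked by the naming rule, turned its direction. The direction of the other called genes was not examined one by one. The balance of higher and lower calls, near even except for the difference, is not firm. It turned in edgeR and with a 2-fold minimum in all 5 other comparisons, after the GC and length correction for TGFβ in WT and KO, after rescaling for TGFβ in KO and KO against WT under SB505124, and for TGFβ in KO also in other fits. Against calls of 5416 genes for TGFβ in WT, 3864 in KO, 352 for the difference, 7117 and 7865 for KO against WT under SB505124 and TGFβ, and 6477 averaged, a 2-fold minimum left 750, 712, 74, 1880, 2056 and 715, as it must. The difference gave 134 genes without a filter, 47 without a variance trend and 666 after the GC and length correction, and 141 to 1027 with single libraries left out (1027 without WT TGFβ replicate 1). Leaving out single libraries gave 2320 to 4410 genes for KO; the lone library of a group is then assumed to vary like the others, and the cause was not tested. Without chromosomes 4 and 14, 58.1% of the 6142 genes called under SB505124 were higher in KO, against 51.4%. Rescaling on genes of mean at least 100 put the Rreb1 level in every library, mean of KO_SB, at 1322 against 1335. The replicate number as a block gave 5359, 3658, 252, 7103, 7835 and 6383 genes, and replicate deviations of the groups correlated by -0.20 to 0.20, which does not establish a pairing. With the block the fibrogenic list under TGFβ had an adjusted p of 0.0527. Replicate differences followed GC content in KO under SB505124 (rank correlation -0.54) and WT under TGFβ (0.45). The log2 fold changes followed it by 0.26 for TGFβ in WT, 0.36 in KO and 0.09 for the difference. For KO against WT these values were -0.21 under SB505124 and -0.14 under TGFβ. With transcript length the rank correlations were -0.24 for TGFβ in WT, -0.14 in KO and 0.19 for the difference. For KO against WT those with length were 0.12 under SB505124 and 0.18 under TGFβ. The GC and length correction, on 11922 genes, shared 4349 of the 5416 calls for TGFβ in WT and 2965 of the 3864 in KO. Over all alternatives for named genes 13291 values stayed on their side of the threshold, called or not, 508 lost a call (202 with the 2-fold minimum) and 113 gained one; for lists these were 1701, 48 and 71. No list call held with an estimated correlation. Fry, which does not compare a list with other genes, called 19 of 26 lists for TGFβ in WT, 19 in KO and 4 for the difference. For KO against WT it called 16 under SB505124 and 19 under TGFβ. A gene with 10 reads has a counting error of 31.6%.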

Other observations

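The groups below were formed from symbol letters (382 families) and by on or off state only after the values were seen. In WT, 37 of 46 Rpl genes rose under TGFβ (median 0.39, camera adjusted p = 1.7e-09, and adjusted p = 0.985 with an estimated correlation). The difference of responses passed for 2 of the 46, both lower in KO-labelled cells (median over the family -0.27, adjusted p = 2.9e-12, and adjusted p = 0.977 with an estimated correlation). Under TGFβ 43 of 46 were lower in KO-labelled libraries (median -0.56, adjusted p = 8.3e-09, and adjusted p = 0.996 with an estimated correlation). In WT, 18 of 21 Cox genes rose (median 0.44) and 18 of 28 Kif genes fell (median -0.29). All 10 Serpinb genes were lower in KO-labelled libraries under SB505124 (median -1.54, adjusted p = 0.00167) and all 7 Ugt genes higher (median 1.93, adjusted p = 0.00547), each with adjusted p = 0.998 with an estimated correlation. No family was called with an estimated correlation. After the GC and length correction the camera adjusted p of the Rpl family was 1.0e-06 in WT and 2.7e-09 for the difference. For Rpl in KO-labelled against WT libraries it was 1.5e-06 under TGFβ, and under SB505124 a call (0.00547) was lost (0.0761). In WT the corrected value was 0.00184 for Cox and 0.00633 for Kif. Under SB505124 it was 5.8e-04 for Serpinb and 0.0279 for Ugt.

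With a mean of at least 50 in the higher genotype under SB505124 and a log2 difference above 4 in both treatments, 108 genes were nearly off in KO-labelled libraries and 44 in WT. Of the 108, 16 lie on chromosomes 4 and 14 (14.8%, against 9.5% of eligible genes), and 4 pairs were neighbours, against a mean of 0.91 in 1000 random draws of which 13 had as many. Of the 44, none lies on those chromosomes, against 9.2% of eligible genes. They held 1 pair of neighbours, against a mean of 0.16 in 1000 draws of which 149 had as many. The lower values across both chromosomes can by themselves raise the share for the 108 and lower it for the 44.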
